A study of Intrasporangium calvum with 48 samples.

How the data were processed

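RNA was sequenced from pelleted cells of Intrasporangium calvum C5. Per the labels' protocols, ribosomal RNA was depleted with the Ribo-Zero Bacteria kit, libraries were made with a stranded TruSeq kit and paired reads were taken on a HiSeq. Trimmomatic, STAR, HTSeq and DESeq2 are named in the submitters' processing notes, without versions or settings. The genome build, annotation, strand setting of the counting and handling of reads shared by similar or overlapping genes are not given in the sources used here, so counts of such genes are uncertain. The series text states that several sequencing runs were combined per library, and the counts are not split by run.

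The authors deposited a table of whole-number counts per gene, which was used for all main tests, and a table of variance-stabilised values on a log2 scale, which was used in 1 alternative. That the second table is on the log2 scale was read from the values: among highly expressed genes its slope on log2 counts lay between 0.998 and 1.000. Groups were taken from the sample titles, which match the headers of the deposited counts. Each column of the deposited log2 table was compared with each count column by rank correlation across genes. 45 columns matched the count column of the same name, and 3, all injection libraries numbered 1, matched another. The column headed sulfide 23 hours ranked as sulfide 10 hours in the counts, cysteine 23 hours as sulfide 23 hours, and sulfide 10 hours as cysteine 23 hours. These 3 columns were left out of that alternative. The other columns of both tables were all used.

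Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered by filterByExpr on the 16 groups, libraries were scaled by TMM factors, and 1 quasi-likelihood model with a mean per group was fitted to all 48 libraries with robust estimation. Each comparison was an F-test of 1 contrast, and each interaction an F-test of 3 contrasts jointly (the effect at mid log, late log and stationary phase, each minus that at early log). In all 25 tests were run. P-values were adjusted by the Benjamini-Hochberg method over the genes within each test, and a gene was called at an adjusted p under 0.05 with no minimum fold. CPM values use TMM-scaled library sizes. Principal components, correlations between libraries and the CPM equal to 3 counts use library totals alone. Standard errors of log2 fold changes were derived from the F statistic.

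The rule for named genes was set before the data were examined. Because the files do not pair identifiers with names, at most 2 identifiers higher and 2 lower are given per comparison: those called, with all 3 libraries of 1 group above all 3 of the other, a mean of at least 20 CPM in the higher group, and the largest log2 fold changes. Chance alone puts 3 libraries above or below the 3 others for 10% of genes. For each interaction the 2 smallest p-values are given. Gene lists fixed in advance could not be matched to identifiers and were not run. A fold against a group without counts is a lower bound with a floor of 3 counts over the group, and 3 counts equal between 0.383 and 2.10 CPM over the libraries. Intervals and floors cover counting error only.

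In each group, counts were checked for libraries deposited more than once. The smallest chi-square per degree of freedom over 48 pairs was 6.72, so no pair agreed within sampling noise. The test was also tested on simulated data for the comparison of the cysteine supplement with Regular at mid log (3615 genes). It called 35 of 67 genes changed 1.5-fold, 59 of 67 changed 2-fold and 63 of 66 changed 4-fold, all in the simulated direction, and 5 unchanged genes. The simulated interaction of cysteine and phase, over the same genes, recovered 118 of 200 changed genes and called 8 unchanged genes. The simulation gave every group the same spread per gene and changed only these 200 genes, about equally up and down. They were drawn from genes with at least 20 CPM in Regular at mid log and were changed at that phase alone. The simulation does not show how often changes of genes at lower levels are found. Nor does it show how the test errs where groups differ in spread or where most genes change. Alternatives were other scalings, filters and tools (DESeq2 1.42.0, and limma 3.58.1 on the deposited log2 values), a minimum fold, fits of the compared groups alone, a replicate block, other reference phases, and omission of libraries. Scaling by library totals alone and omission of the 6 libraries labelled 23 hours were chosen after seeing the data. Chance values for effects that share Regular libraries came from 20 simulations of unchanged groups.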

Results

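Transcript levels were measured by RNA sequencing in Intrasporangium calvum strain C5, an actinobacterium grown without oxygen on 30 mM nitrate and 20 mM lactate. The 48 libraries fell into 16 groups of 3. Cultures without added reduced sulfur (Regular), with 0.25 mM cysteine from the start (cysteine supplement) and with 0.25 mM sulfide from the start (sulfide supplement) were each sampled at early log, mid log, late log and stationary phase. Further cultures grew to mid log and were then injected with 1 mM cysteine or 1 mM sulfide, with libraries labelled 10 hours and 23 hours. The series addressed how reduced sulfur compounds inhibit growth of a denitrifier. The labels give replicate numbers but do not say whether replicates were separate cultures, so p-values rest on a spread between libraries that may be partly technical. That spread was estimated for each gene over all 16 groups together, so it is not that of the compared libraries alone. Total counts ran from 1428456 to 7822878 per library, and the 3 smallest libraries, all labelled 10 hours, held 1428456, 2357034 and 2740758. Levels are given as counts scaled to library size (CPM). A library detected between 3628 and 3674 of the 3687 genes. Of the genes in the table, 3628 were tested. For each identifier picked for the size of its change in a comparison of 2 groups, all 3 libraries of one group lay above all 3 of the other. This was not required of values added for such identifiers from other phases or groups. The count table identifies genes by identifier and does not pair identifiers with gene names, so genes are given by identifier and no function is stated.

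Libraries of 1 group lay close together. Their log2 CPM correlated with r between 0.955 and 0.995 across genes, and for 48 of 48 libraries the most similar library belonged to the same group. The first principal component held 43.8% of the variance and the second 14.8%. On the first, the group mean was -14.0 for Regular at stationary phase and 95.9 for the cysteine supplement at that phase. The components were computed on CPM scaled by library totals alone. Between these 2 groups that scaling moved the median log2 fold change of all genes by -0.73 from that under TMM. Part of their distance may therefore be such a shift. The 10 most abundant genes of each library took 23.6% ± 2.31 of counts in the cysteine supplement at stationary phase (SD, n = 3) and 11.8% ± 1.79 in Regular. In the libraries labelled cysteine injection at 23 hours the most abundant gene of each library took 11.3% ± 2.49 of its counts.

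**Figure D1:**
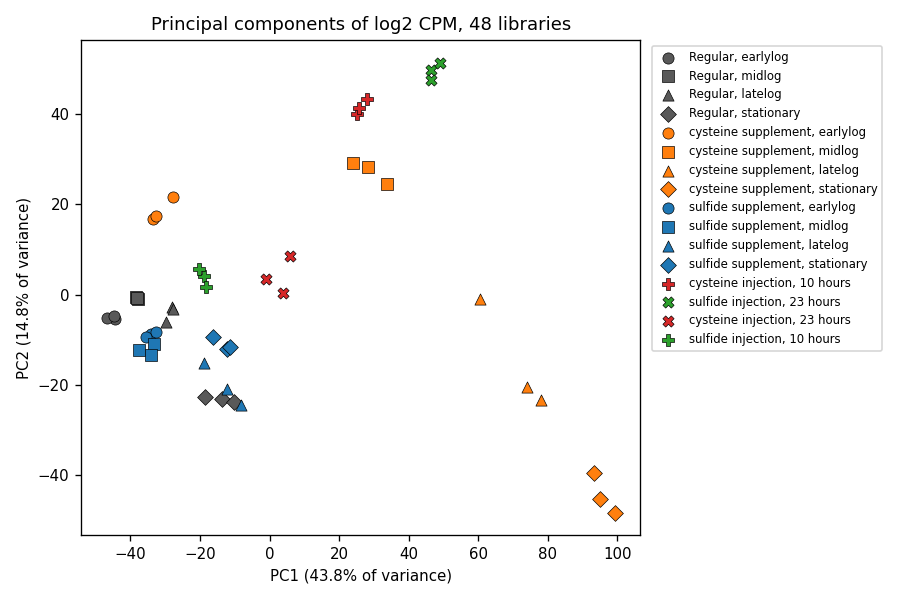
Principal components of log2 CPM, scaled by library totals alone, for the 48 libraries. The first component is on the horizontal axis and the second on the vertical axis. Each point is a library, coloured by treatment and shaped by phase or hours; the cysteine supplement at stationary phase lies farthest right, at a mean of 95.9.

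Cysteine present from the start was compared with Regular at each phase. Ga0242637_11191 and Ga0242637_112130 were the most strongly raised identifiers at early log, late log and stationary phase. At early log Ga0242637_11191 stood at 82.6 ± 46.9 against 0.955 ± 0.208 CPM (SD, n = 3 each, log2 fold change 6.40, SE 0.45, edgeR adjusted p = 8.76e-14), and Ga0242637_112130 at 175 ± 60.5 against 3.76 ± 1.02 CPM (SD, n = 3 each, log2 fold change 5.54, SE 0.30). At mid log Ga0242637_11191 stood at 2898 ± 218 against 0.952 ± 0.137 CPM (SD, n = 3 each, log2 fold change 11.55, SE 0.50, edgeR adjusted p = 5.34e-21). It remained near that level at late log (log2 fold change 11.71, SE 0.50) and stationary phase (log2 fold change 11.66, SE 0.51). Ga0242637_112130 was raised by a log2 fold change of 10.77 (SE 0.35) at late log and 11.59 (SE 0.37) at stationary phase. Ga0242637_113384 had 2 counts in the 3 Regular libraries at mid log and 4352 in the 3 with cysteine. Its ratio was 2835 (95% exact binomial interval 784 to 23416, counting error alone).

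Ga0242637_11954 and Ga0242637_113590 fell most at early and mid log. Ga0242637_11954 stood at 3.07 ± 0.974 against 763 ± 268 CPM (SD, n = 3 each) at early log (log2 fold change -7.92, SE 0.75, edgeR adjusted p = 3.1e-10) and at 2.94 ± 0.911 against 1951 ± 166 CPM (SD, n = 3 each) at mid log (log2 fold change -9.42, SE 0.80). Ga0242637_113590 changed by a log2 fold change of -7.24 (SE 0.68), -8.49 (SE 0.72) and -8.70 (SE 0.73) at early, mid and late log. Its neighbour by identifier, Ga0242637_113589, fell at late log (log2 fold change -8.51, SE 0.74). At stationary phase the leading decreases were Ga0242637_11647, with no count in any cysteine library and 641 in the Regular libraries, at least 117-fold lower against a floor of 3 counts over the group, and Ga0242637_11649 (log2 fold change -7.85, SE 0.64).

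By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 751 genes differed from Regular at early log (438 higher and 313 lower), 2296 at mid log (1132 higher and 1164 lower), 2717 at late log (1384 higher and 1333 lower) and 2949 at stationary phase (1533 higher and 1416 lower). Of these, 245, 1020, 1634 and 2103 changed by a log2 fold change of at least 1 in size. In 22 of the 23 comparisons of 2 groups the direction with more calls turned under at least 1 alternative (fold minimum aside). Their splits without a fold minimum therefore do not settle a direction. The exception was cysteine at early log, with more genes higher than lower under each alternative run. TMM and DESeq2 size factors place the typical gene near no change, which by itself brings splits near even. Such relative levels cannot show whether most genes rose or fell together. With a minimum log2 fold change of 1 some splits leaned further. Sulfide against Regular at stationary phase had 275 higher and 98 lower, and Regular late log against mid log 117 and 22. Others were near even, such as sulfide against Regular at early log with 225 and 226. The splits of these larger changes were not run under the other alternatives. Scaling by library totals alone, chosen after seeing the data, gave 568 higher and 159 lower at early log, 922 higher and 1801 lower at late log and 994 higher and 1965 lower at stationary phase, and no filter gave 1345 higher and 1631 lower at stationary phase. The early-log count was 445 without replicate 1 of the cysteine group and 1171 when the 6 libraries compared were fitted alone. Across the phases, which share no libraries, 178 genes were higher in all 4 and 141 lower in all 4, where independent lists of these sizes would share 22.0 and 14.4. The tests do share the spread estimate of each gene, so a gene with little spread is called more readily in all, which can raise such overlaps.

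Whether the cysteine effect differed between phases was tested by the interaction of supplement and phase. Ga0242637_113530 had a log2 fold change against Regular of 0.03 (SE 0.14) at early log, -0.42 (SE 0.14) at mid log, 0.67 (SE 0.14) at late log and 5.84 (SE 0.17) at stationary phase (edgeR interaction adjusted p = 1.82e-23). Ga0242637_1166 had -0.30 (SE 0.17), 2.58 (SE 0.16), 3.41 (SE 0.17) and 6.36 (SE 0.19) at the same phases (interaction adjusted p = 2.38e-21). The interaction was called for 3182 genes.

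With sulfide from the start, Ga0242637_113650 rose at early log to 42.9 ± 22.1 against 1.21 ± 1.18 CPM (SD, n = 3 each, log2 fold change 5.09, SE 0.52, edgeR adjusted p = 1.15e-09). Ga0242637_112413 rose at early log (log2 fold change 5.01, SE 0.51) and at late log, where it stood at 3338 ± 1395 against 151 ± 17.4 CPM (SD, n = 3 each, log2 fold change 4.47, SE 0.48). At mid log Ga0242637_11583 stood at 560.1 ± 715 against 21.1 ± 2.03 CPM (SD, n = 3 each, log2 fold change 4.73, SE 0.91, edgeR adjusted p = 5.81e-05) and Ga0242637_113248 at 1079 ± 892 against 51.9 ± 9.15 CPM (SD, n = 3 each, log2 fold change 4.38, SE 0.43). The log2 fold change of Ga0242637_112413 was -0.19 (SE 0.44) at mid log and -1.64 (SE 0.42) at stationary phase, and that of Ga0242637_113248 was -2.47 (SE 0.42) at early log and -0.03 (SE 0.37) at stationary phase, while at late log it stood at 64.9 ± 2.81 CPM with sulfide and 32.2 ± 2.83 CPM without (SD, n = 3 each). Ga0242637_112079 led at late log with 2768 ± 1261 against 96.5 ± 11.5 CPM (SD, n = 3 each, log2 fold change 4.84, SE 0.51). At stationary phase Ga0242637_111699 stood at 316 ± 216 against 24.4 ± 29.7 CPM (SD, n = 3 each, log2 fold change 3.67, SE 0.52, edgeR adjusted p = 1.54e-06) and its neighbour by identifier Ga0242637_111698 at 289 ± 131 against 27.8 ± 27.9 CPM (SD, n = 3 each, log2 fold change 3.36, SE 0.44). In an edgeR fit of the 6 compared libraries alone Ga0242637_111699 was not called (adjusted p = 0.0635), and over all alternatives its adjusted p ran from 1.67e-12 to 0.0802. With a replicate block added to such fits, Ga0242637_11583, Ga0242637_113248 and Ga0242637_111698 were not called either (edgeR adjusted p = 0.0798, 0.0655 and 0.0584).

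Sulfide lowered Ga0242637_111208 at early log to 20.9 ± 2.55 against 438 ± 88.7 CPM (SD, n = 3 each, log2 fold change -4.39, SE 0.51, edgeR adjusted p = 2.16e-08) and Ga0242637_113553 to 164 ± 31.1 against 2648 ± 323 CPM (SD, n = 3 each, log2 fold change -4.02, SE 0.40). Ga0242637_11839 fell at mid log (log2 fold change -4.02, SE 0.40) but not at late log, where its log2 fold change was 1.17 (SE 0.35). Ga0242637_111938 fell at mid log (log2 fold change -3.18, SE 0.46). It fell further at stationary phase, to 12.1 ± 7.22 against 799.6 ± 301 CPM (SD, n = 3 each, log2 fold change -6.02, SE 0.43, edgeR adjusted p = 1.78e-13). Ga0242637_11615 fell at stationary phase to 109 ± 41.5 against 7004 ± 2380.2 CPM (SD, n = 3 each, log2 fold change -6.00, SE 0.41). At late log the largest decreases were Ga0242637_113651 (log2 fold change -4.20, SE 0.70) and Ga0242637_113684 (log2 fold change -4.16, SE 0.67).

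Sulfide changed 1387 genes at early log (692 higher and 695 lower), 1787 at mid log (868 and 919), 1471 at late log (593 and 878) and 1518 at stationary phase (820 and 698). A log2 fold change of at least 1 in size was reached by 451, 587, 461 and 373 of them. Library totals alone gave 622 higher and 1154 lower at mid log and 1150 higher and 324 lower at stationary phase, while DESeq2 size factors gave 713 higher and 663 lower at late log and 737 higher and 814 lower at stationary phase. With no filter the splits were 775 higher and 598 lower at late log and 707 higher and 852 lower at stationary phase, and the DESeq2 test gave 742 higher and 834 lower at the latter. Without replicate 2 of Regular at stationary phase the split there was 573 higher and 687 lower, and without replicate 3 it was 592 higher and 780 lower. The stationary count was 293 when the 6 libraries compared were fitted alone. For 97.3%, 97.65%, 97.2% and 71.9% of the genes called at the 4 phases, the 3 libraries of 1 group lay above the 3 of the other. The calls came from the same libraries and favour such separation, so these shares are no separate evidence for them. Genes higher in all 4 phases numbered 39 and genes lower in all 4 numbered 63, against 6.12 and 8.20 for independent lists. The phases share the spread estimate of each gene, which can raise such overlaps. The interaction of sulfide and phase was called for 2479 genes. Ga0242637_113646 had a log2 fold change of -3.75 (SE 0.25), 1.07 (SE 0.22), -2.26 (SE 0.23) and -0.42 (SE 0.22) at early log, mid log, late log and stationary phase (edgeR interaction adjusted p = 5.25e-13), and Ga0242637_11616 had 0.17 (SE 0.15), -1.47 (SE 0.15), -0.36 (SE 0.15) and -2.86 (SE 0.16) (interaction adjusted p = 5.96e-13).

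The cysteine and sulfide effects at a phase were measured against the same Regular libraries. Across genes their log2 fold changes correlated with r = 0.301, 0.159, 0.472 and 0.378 at early log, mid log, late log and stationary phase, where simulated groups without any effect gave 0.497, 0.470, 0.459 and 0.472. The covariances were 0.167, 0.180, 0.660 and 0.597, against simulated values of 0.0353, 0.0353, 0.0350 and 0.0353. Genes higher with both compounds numbered 158, 302, 387 and 479 in the same order of phases, against 83.5, 271, 226 and 346 for independent lists, and genes lower with both numbered 130, 337, 562 and 451, against 60.0, 295, 323 and 272. Genes called in opposite directions numbered 107, 534, 238 and 330, against 144, 565, 553 and 615. At late log the simulations averaged 0 genes higher with both and 0.05 lower with both. Only at late log was r above the simulated value, while the covariance was above it at all 4 phases. The simulated r arises from the shared libraries alone, so an r below it does not show that the effects disagree. The simulations gave all groups the same spread per gene, so the simulated covariance may be too low at stationary phase. Chi-square per degree of freedom ran from 109 to 255 between Regular libraries there and from 7.53 to 19.9 at other Regular phases. The 3 shared Regular libraries per phase were too few to split, and genes are not independent replicates.

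The compounds were compared directly at the same 0.25 mM dose. Ga0242637_113324 was higher with cysteine at early log, at 8263 ± 717 against 19.0 ± 1.31 CPM (SD, n = 3 each, log2 fold change 8.77, SE 0.98, edgeR adjusted p = 4.69e-09), as was Ga0242637_113325 (log2 fold change 7.32, SE 0.82). Ga0242637_11191 was higher with cysteine at mid log (log2 fold change 10.51, SE 0.48), late log (log2 fold change 10.96, SE 0.48) and stationary phase, where it stood at 3772 ± 450.4 against 1.81 ± 0.740 CPM (SD, n = 3 each). Ga0242637_113384 stood at 277 ± 41.3 against 0.232 ± 0.201 CPM (SD, n = 3 each) at mid log, with at most 2 counts in any sulfide library. Ga0242637_112130 was higher at late log (log2 fold change 10.48, SE 0.35) and stationary phase (log2 fold change 10.83, SE 0.35). Ga0242637_11954 and Ga0242637_113590 were lower with cysteine at early log (log2 fold change -4.79, SE 0.68, and log2 fold change -4.56, SE 0.61) and at mid log (log2 fold change -8.80, SE 0.79, and log2 fold change -7.79, SE 0.71). Ga0242637_113590 and Ga0242637_113589 were lower at late log (log2 fold change -8.88, SE 0.74, and log2 fold change -8.33, SE 0.74). At stationary phase Ga0242637_11376 had 1 count with cysteine and 487 with sulfide, a ratio of 197 (95% exact binomial interval 35.2 to 7808), and Ga0242637_111695 was lower with cysteine at 55.0 ± 1.52 against 3548 ± 1941 CPM (SD, n = 3 each, log2 fold change -6.01, SE 0.63). Calls numbered 1453 at early log (733 higher with cysteine and 720 lower), 2484 at mid log (1214 and 1270), 2569 at late log (1332 and 1237) and 2895 at stationary phase (1484 and 1411). Library totals alone gave 816 higher and 505 lower, 793 higher and 1799 lower and 791 higher and 2179 lower at early log, late log and stationary phase.

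Injected cultures were compared with Regular at mid log, the phase of injection. The labels name no uninjected group of matching hours, so time and injection cannot be separated in these comparisons. In the libraries labelled cysteine injection at 10 hours, Ga0242637_11191 rose to 2215 ± 689 against 0.952 ± 0.137 CPM (SD, n = 3 each, log2 fold change 11.16, SE 0.50, edgeR adjusted p = 1.08e-20). Ga0242637_113384 had 2305 counts against 2 in Regular, a ratio of 2421 (95% exact binomial interval 669 to 20003). Ga0242637_11954 fell to 5.21 ± 2.12 against 1951 ± 166 CPM (SD, n = 3 each, log2 fold change -8.44, SE 0.78), and Ga0242637_11374 fell to 0.654 ± 0.582 against 311 ± 31.5 CPM (SD, n = 3 each, log2 fold change -8.43, SE 0.78). In the libraries labelled sulfide injection at 10 hours, Ga0242637_113154 rose to 1442 ± 272 against 3.20 ± 0.829 CPM (SD, n = 3 each, log2 fold change 8.80, SE 0.43, edgeR adjusted p = 1.21e-17) and Ga0242637_112217 to 369 ± 21.1 against 11.4 ± 2.79 CPM (SD, n = 3 each, log2 fold change 5.02, SE 0.45), while Ga0242637_11374 (log2 fold change -8.06, SE 0.69) and Ga0242637_11372 (log2 fold change -8.02, SE 0.72) fell.

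The libraries labelled 23 hours were compared with the same Regular libraries. With the cysteine label, Ga0242637_111703 stood at 13717 ± 3988 CPM (SD, n = 3, log2 fold change 9.74, SE 0.82, edgeR adjusted p = 2.51e-12 against Regular) and Ga0242637_111707 at 3742 ± 807 against 6.05 ± 1.70 CPM (SD, n = 3 each, log2 fold change 9.26, SE 0.65), and Ga0242637_113589 (log2 fold change -7.88, SE 0.73) and Ga0242637_11372 (log2 fold change -7.64, SE 0.72) were lowest. With the sulfide label, Ga0242637_11191 stood at 8745 ± 488 against 0.952 ± 0.137 CPM (SD, n = 3 each, log2 fold change 13.14, SE 0.52, edgeR adjusted p = 2.92e-22), and Ga0242637_113384 had 12999 counts against 2, a ratio of 11865 (95% exact binomial interval 3284 to 97980). Ga0242637_11345 fell to 2.86 ± 0.548 against 1765 ± 168 CPM (SD, n = 3 each, log2 fold change -9.26, SE 0.49) and Ga0242637_11344 to 29.4 ± 12.9 against 13476 ± 1249 CPM (SD, n = 3 each, log2 fold change -8.84, SE 0.47). Calls against Regular numbered 2419 for cysteine at 10 hours (1205 higher and 1214 lower), 2298 for cysteine at 23 hours (1247 and 1051), 1378 for sulfide at 10 hours (723 and 655) and 2732 for sulfide at 23 hours (1355 and 1377). At 23 hours library totals alone gave 544 higher and 1841 lower for cysteine and 985 higher and 1788 lower for sulfide. With Regular at stationary phase as the reference, the sulfide count at 10 hours was 2156.

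Between the compounds at 10 hours, Ga0242637_11191 (log2 fold change 10.81, SE 0.50, edgeR adjusted p = 4.4e-20) and Ga0242637_112674 (log2 fold change 10.27, SE 0.37) were higher in the cysteine libraries, and Ga0242637_113154 (log2 fold change -6.59, SE 0.39) and Ga0242637_113473 (log2 fold change -3.88, SE 0.23) were higher in the sulfide libraries. At 23 hours the libraries labelled sulfide held more of Ga0242637_11191, at 4.80 ± 1.88 against 8745 ± 488 CPM (SD, n = 3 each) for cysteine against sulfide (log2 fold change -10.84, SE 0.48, edgeR adjusted p = 5.46e-21), and more of Ga0242637_112674 (log2 fold change -10.03, SE 0.35). The libraries labelled cysteine held more of Ga0242637_111703 (log2 fold change 10.24, SE 0.85) and Ga0242637_111701 (log2 fold change 9.62, SE 0.72). Calls numbered 2219 at 10 hours (1106 higher in cysteine and 1113 lower) and 2579 at 23 hours (1335 and 1244). Across genes, the contrast of cysteine with sulfide at 10 hours correlated with that of the supplements at mid log (r = 0.611), with 698 genes higher in both and 749 lower in both, where independent lists would share 370.1 and 389.6. The contrast at 23 hours correlated with that at 10 hours with r = -0.555, and 1394 genes were called in opposite directions, where independent lists would give 789. With the supplements at mid log r was -0.406. These contrasts share no libraries but do share the spread estimate of each gene, and genes are not independent replicates.

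**Figure D2:**
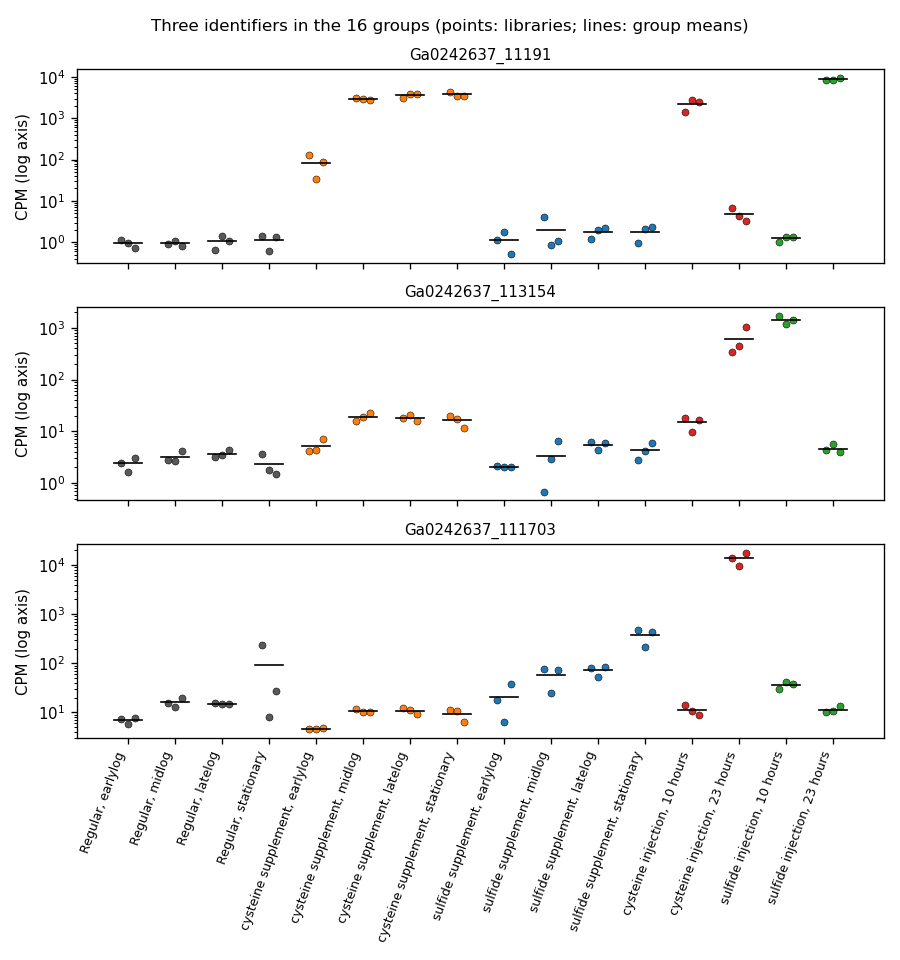
CPM on a log axis of 3 identifiers in the 16 groups, picked for this plot after their values were seen; points are libraries and lines are group means of 3. Ga0242637_11191 averaged 2215 ± 689 CPM (SD) in the libraries labelled cysteine at 10 hours and 8745 ± 488 CPM in those labelled sulfide at 23 hours; Ga0242637_113154 averaged 1442 ± 272 CPM in those labelled sulfide at 10 hours and 603 ± 365 CPM in those labelled cysteine at 23 hours.

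From 10 to 23 hours, libraries labelled cysteine gained Ga0242637_111703 (log2 fold change 10.35, SE 0.86, edgeR adjusted p = 1.48e-12) and Ga0242637_111707 (log2 fold change 9.35, SE 0.69) and lost Ga0242637_11191 (log2 fold change -8.86, SE 0.45) and Ga0242637_112130 (log2 fold change -8.59, SE 0.33). Those labelled sulfide gained Ga0242637_11191 (log2 fold change 12.79, SE 0.52, edgeR adjusted p = 4.62e-22) and Ga0242637_112674 (log2 fold change 11.88, SE 0.38) and lost Ga0242637_11345 (log2 fold change -8.49, SE 0.48) and Ga0242637_113154 (log2 fold change -8.27, SE 0.43). The cysteine libraries differed in 2162 genes (1104 higher and 1058 lower at 23 hours) and the sulfide libraries in 2698 (1310 and 1388). Library totals alone gave 528 higher and 1729 lower for cysteine and 912 higher and 1779 lower for sulfide.

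Growth without added sulfur compounds served as the background. From early to mid log, Ga0242637_11839 rose to 158 ± 36.8 against 19.1 ± 4.11 CPM (SD, n = 3 each, log2 fold change 3.04, SE 0.38, edgeR adjusted p = 9.61e-07) and Ga0242637_112019 rose (log2 fold change 2.47, SE 0.52), while Ga0242637_11102 (log2 fold change -2.93, SE 0.26) and Ga0242637_111866 (log2 fold change -1.99, SE 0.26) fell. From mid to late log, Ga0242637_113684 (log2 fold change 4.47, SE 0.68) and Ga0242637_113651 (log2 fold change 3.71, SE 0.68) rose, and Ga0242637_11101 (log2 fold change -3.32, SE 0.53) and Ga0242637_112941 (log2 fold change -2.72, SE 0.55) fell. Entry into stationary phase raised Ga0242637_113249 to 8274 ± 4977 against 78.5 ± 13.0 CPM (SD, n = 3 each, log2 fold change 6.72, SE 0.51, edgeR adjusted p = 4.64e-13) and Ga0242637_113248 (log2 fold change 6.48, SE 0.47), and lowered Ga0242637_112656 (log2 fold change -5.66, SE 0.66) and Ga0242637_112657 (log2 fold change -5.37, SE 0.74). Calls numbered 710 from early to mid log (392 higher and 318 lower), 417 from mid to late log (246 and 171) and 1856 from late log to stationary phase (813 and 1043). Library totals alone gave 235 higher and 410 lower for the first step and 632 higher and 1193 lower for the third. The split of the third step turned to 974 higher and 852 lower with DESeq2 size factors, 1050 higher and 780 lower with no filter, 911 higher and 663 lower without stationary replicate 2 and 996 higher and 717 lower without stationary replicate 3. Leaving out mid-log replicates 1, 2 and 3 in turn lowered the second count to 175, 171 and 246, and leaving out late-log replicates 1, 2 and 3 to 182, 203 and 257. Leaving out early-log replicate 2 lowered the first to 465, and fitting the compared libraries alone gave 1648, 1484 and 1276 for the 3 steps.

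**Figure D3:**
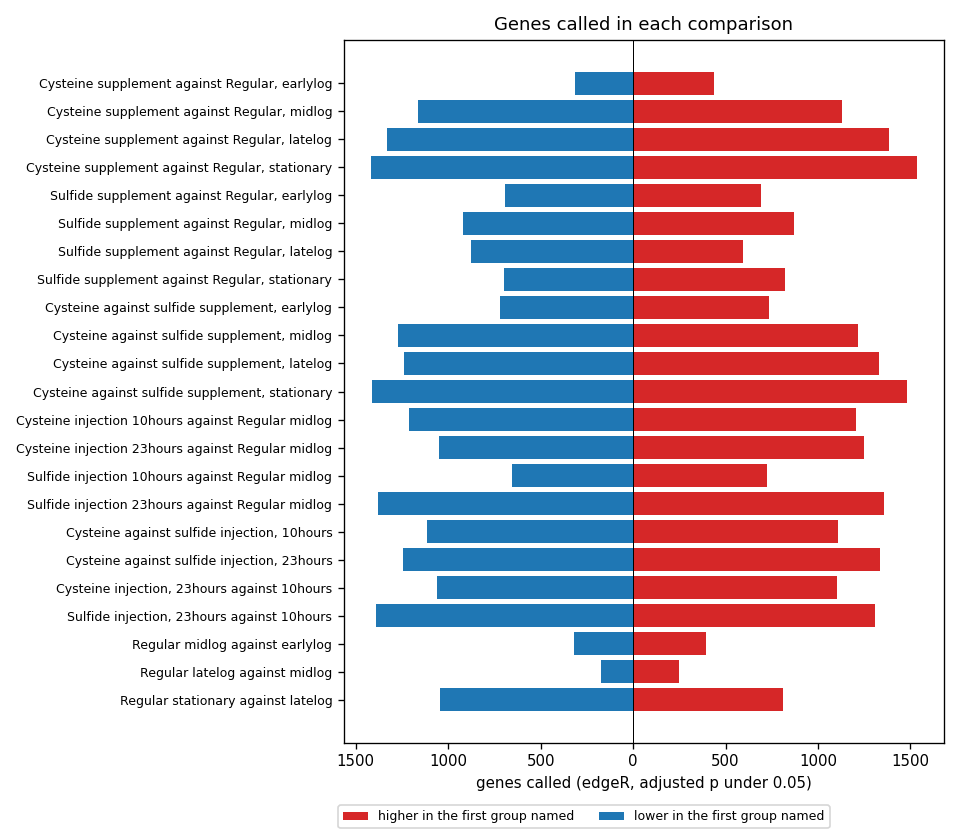
Number of genes called in each of the 23 comparisons by edgeR, on a linear axis that starts at 0 in the middle. Bars to the right count genes higher in the first group named and bars to the left genes lower in it; the largest total is 2949, for the cysteine supplement at stationary phase.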

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

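The comparisons of depths and of scalings between phases were chosen only after the result was seen. The effect of each supplement differed between growth phases by a test of the difference itself. The interaction with phase was called for 3182 genes with cysteine and 2479 with sulfide. In fits of the 24 libraries concerned, treatment labels were exchanged within phases in 100 draws that include the real labels. For cysteine 1 of the 100 draws gave as many calls, with 3195 for the real labels and 2823 for the highest other, and for sulfide 2 of 100, with 2481 and 2499, so that 1 other draw exceeded the real labels. The draws mix supplemented and Regular libraries and so also break up an effect common to all phases, and they do not decide whether chance can be excluded for the interaction.

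Calls of cysteine against Regular went from 751 at early log to 2949 at stationary phase, a ratio of 3.93. In fits of the compared groups alone the counts were 1171 and 2616, a ratio of 2.23, and without replicate 1 of the early-log cysteine libraries the early-log count was 445, so the size of the ratio is not firm. Greater depth at stationary phase as the cause is argued against by the totals, whose mean at stationary phase was 0.828 times that at early log with cysteine and 0.987 times in Regular. No stationary library was more than 1.16 times as deep as an early-log library of its group. A few genes that take many counts would act on the others through the scaling. Library totals alone, which leave this in, moved the median log2 fold change of all genes at stationary phase by -0.73 from that under TMM and gave a ratio of 4.07. The ratios of 3.93 under TMM and 3.84 under DESeq2 size factors, which correct for such genes, argue against them as the whole cause. The median absolute log2 fold change of called genes was 0.71, 0.92, 1.19 and 1.53 at early log, mid log, late log and stationary phase, over lists that differ between phases. Together with the interaction this leaves a cysteine effect that differs in size with phase as a hypothesis. Cultures at unequal ages under 1 phase label were not tested.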

How the results depend on the processing

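Scaling by library totals alone and the omission of the 6 libraries labelled 23 hours were chosen only after the data were seen. The 96 values of named identifiers kept their direction under every alternative run, and their calls under all except the fits of the compared groups alone, where Ga0242637_111699 lost its call without the replicate block (log2 fold change 3.61, 3.67 in the fit of all libraries). With the block, calls were lost by Ga0242637_111699 (4.08 against 3.67), Ga0242637_111698 (3.66 against 3.36), Ga0242637_11583 (3.88 against 4.73) and Ga0242637_113248 (3.99 against 4.38). Named identifiers were picked from these same data for the largest changes or smallest p-values. Their kept directions were thus close to fixed in advance and say little about other genes. All 25 counts stayed within 1.5 times under DESeq2 size factors, the DESeq2 test, limma on the deposited log2 values, both other filters, library totals alone and the replicate block in the fit of all libraries. The direction with more calls was less stable: it turned in 11 of 23 comparisons under DESeq2 size factors, 10 under library totals alone, 16 with no filter, 16 in fits of the compared groups alone and 15 without at least 1 of the single libraries. With library totals alone the median log2 fold change of all genes moved by up to -0.91 (cysteine against sulfide supplement at stationary phase), and changes are given relative to TMM. All counts of the 20 tests without libraries labelled 23 hours stayed within 1.5 times when those 6 libraries were left out, as did the 8 injection counts without the 3 libraries whose headers differ between the tables.

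With a minimum log2 fold change of 1 the counts fell to 245, 1020, 1634 for cysteine against Regular at early, mid and late log, 451, 587, 461, 373 for sulfide at the 4 phases, 496, 1268, 1451 between the supplements at early, mid and late log, 1185 and 1046 for cysteine injection at 10 and 23 hours, 388 and 1694 for sulfide injection, 1016 and 1471 between the injections, 946 and 1568 from 10 to 23 hours, 135, 139 and 612 for the steps of Regular growth, and 1226 for the sulfide interaction. The construction of this alternative, which drops small changes, is the cause. Fits of the compared groups alone gave 1171 for cysteine at early log, 293 for sulfide at stationary phase, and 1648 and 1484 for the first steps of Regular growth; with the replicate block added, sulfide at stationary phase gave 96 and the steps of Regular growth 1555, 1349 and 908. The fit of all libraries estimates the spread of a gene over all 16 groups together, and the spreads of the groups were unequal. Chi-square per degree of freedom ran from 109 to 255 between Regular libraries at stationary phase and from 7.53 to 19.9 at other Regular phases. With the sulfide supplement it ran from 89.1 to 114 at mid log and from 115 to 136 at stationary phase. At late log it reached 120 with sulfide and 85.5 with cysteine. Whether these unequal spreads caused the moved counts was not tested. With Regular at stationary phase as the reference, sulfide injection at 10 hours gave 2156. Leaving out single libraries gave 445 to 651 for cysteine at early log, 465 to 558 from early to mid log and 171 to 257 from mid to late log of Regular.

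The replicate block in the fit of all libraries gave 2300 calls for cysteine at mid log and 1790 for sulfide. Libraries share only a number: same-numbered deviations correlated between -0.336 and 0.196, in 0 of 23 comparisons were all 3 above 0.1, and in 1 every library correlated best with its own number. The alternatives without ribosomal and transfer RNA and with gene lists were not run, since identifiers are not paired with names. The smaller totals of 3 libraries limit the precision of low genes in the 10-hour groups.

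Each comparison of 3 with 3 libraries has 10 splits, too few for a share under 0.05. The real split of the compared libraries gave 1171, 2598, 2761, 2616 calls for cysteine against Regular at the 4 phases, 1689, 2117, 1788, 293 for sulfide, 1533, 2520, 2484, 2715 between the supplements, 2483, 2304 for cysteine injection, 1828, 2942 for sulfide injection, 2156, 2517 between the injections, 1850, 2793 from 10 to 23 hours and 1648, 1484, 1276 for Regular growth. In each, 1 of the 10 splits, the real one, gave as many; the highest other gave 7 for sulfide at stationary phase and 0 elsewhere.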

Other observations

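The tests of exchanged labels, of a few genes that take many counts, of responses that change with time and of identifier order were chosen only after the result was seen. The contrast of cysteine with sulfide at 23 hours ran opposite to that at 10 hours across genes (r = -0.555; -0.571 to -0.535 with each of the 12 injection libraries left out in turn) and to the supplement contrasts at early log, mid log, late log and stationary phase (r = -0.189, -0.406, -0.390 and -0.381). Ga0242637_11191, raised in every cysteine supplement group, was high in the libraries labelled cysteine at 10 hours and sulfide at 23 hours, while Ga0242637_113154 was high in those labelled sulfide at 10 hours and cysteine at 23 hours. These 2 identifiers were picked after their values were seen, and not all genes followed them. With the cysteine label 145 genes were higher and 165 lower at both hours, where independent lists would share 407 and 382. A candidate explanation is that the compound labels of the 2 groups at 23 hours were exchanged, which needs libraries of both groups to be out of place and gives a negative r with the 10-hour and supplement contrasts, as measured. Wrong labels of the 3 injection libraries numbered 1 alone are argued against by r = -0.528 without them. A few genes that take many counts would move all others one way and give opposite calls in one direction alone. Genes lower with cysteine at 10 hours and higher at 23 hours numbered 705 against 409.6 for independent lists, 1.72 times as many. Genes higher then lower numbered 689 against 379, 1.82 times as many. A shift of all genes left after TMM scaling therefore does not account for the opposite calls. TMM takes out such a shift in advance, so an excess in 1 direction alone was unlikely, and the counts do not decide on the explanation itself. Responses that change between 10 and 23 hours stay open: the change of the sulfide libraries from 10 to 23 hours correlated with the cysteine effect at 10 hours (r = 0.646), which either explanation gives, so these cannot be told apart, and directions at 23 hours rest on the labels as given.

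Under the headers of the log2 table, libraries of the affected groups would correlate less: the lowest r within cysteine at 23 hours would be 0.774 in place of 0.974, and within sulfide at 23 hours 0.786 in place of 0.989. Neighbouring identifiers changed alike. Over 3538 pairs of consecutive identifiers, the profiles over 16 groups correlated with a mean r of 0.443, against at most 0.0282 in 10000 permuted orders (one-sided permutation p = 1e-04, the smallest they can give). Genes in shared transcription units that lie next to each other in identifier order may account for this; identifier order was not checked against a genome.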
